A study of Mus musculus with 47 samples.

How the data were processed

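The analysis started from the deposited table of raw read counts, made by the authors, with 24015 gene symbols and 9 RNA libraries. Per the submitters' processing notes the tools of the series were Bowtie2, TopHat2 2.0.6, MACS2 2.1.1, HTSeq and DESeq2 with the mouse genome mm9; the notes do not say which tool made which file. Per the labels' protocols, jejunum was taken, villus epithelium was released with EDTA, libraries were made with TruSeq RNA V2, which keeps no strand, and 75 bp single-end reads came from a NextSeq 500. Reads of overlapping or antisense genes cannot be told apart in such libraries, and reads of near-identical genes such as Cyp2d, Defa and H2 members may be shared or lost. Of the symbols 22935 are current and 961 older names, and 5966 had no counts in any library. Groups were taken from the labels: WT (n = 2), Cdx2 KO (n = 3), Eed KO (n = 2) and DKO (n = 2). Total counts per library were 30678310 and 18025952 (WT), 19480191, 20959839 and 26447163 (Cdx2 KO), 15727147 and 23934061 (Eed KO), and 31737648 and 20014643 (DKO). The labels call the replicates biological but do not say that they are separate animals, so p values measure the spread between these samples only, and replicate numbers pair nothing. The samples of chromatin assays, 38 in number, were not analysed here.

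Counts were scaled by TMM in edgeR 4.0.16 (R 4.3.3, limma 3.58.1), genes with low counts were removed with filterByExpr (minimum count 10, minimum total 15), which kept 13181 genes and 99.97% of counts, and a quasi-likelihood model was fitted to all 9 libraries with 5 residual degrees of freedom (common biological coefficient of variation 0.289). The comparisons were Cdx2 KO with WT, Eed KO with WT, DKO with WT, DKO with Cdx2 KO, DKO with Eed KO, and the interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes, and also adjusted over each list alone. CPM are counts scaled by TMM to the same library size. Genes with 0 counts in a whole group were given as at least N-fold against 3 counts over its libraries, and with 1 to 3 counts as a ratio with a 95% counting interval. Gene lists, 34 in number, were fixed before the files were read; 31 had at least 5 tested members and were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry. The Hox, pancreas and blood, and sex-linked lists had no list test.

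Genes were named by a rule fixed beforehand. Cdx2 and Eed were always named. In each comparison of 2 groups, the 8 genes with the largest rise and the 8 with the largest fall were named, among those with adjusted p under 0.05, at least 5 CPM in the higher group and no overlap between the libraries of the groups. In the interaction the same rule held without the last condition. Of genes lower in Cdx2 KO and higher in DKO than in Cdx2 KO, the 10 with the largest smaller change were named, and of each list up to 4 members with the smallest p. Symbols of unnamed transcripts were left out of these ranks and stayed in the counts. Unless an overlap or a failed test is stated, every library of one group lay outside the range of the other for the named genes. A gene named in one comparison could be followed in the others. Genes given because they were the few members of a list that passed were chosen after their values were seen.

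Alternatives tried were DESeq2 1.42.0 with its own size factors and test, relative log expression and upper-quartile scaling, no filter and a stricter filter on low counts, fits with only the groups compared, a replicate block, and leaving out each library in turn. Shared libraries between comparisons were imitated with 20 simulations that hold no effect. The scripts were tested on simulated data with known changes: of 100 genes changed 2-fold, 7 were called in Cdx2 KO against WT, 3 in Eed KO against WT, 5 in DKO against WT, 16 in DKO against Cdx2 KO, 7 in DKO against Eed KO and 0 in the interaction. Of 100 changed 4-fold, 67, 50, 70, 71, 60 and 20 were called in that order, with 5, 4, 10, 7, 6 and 0 unchanged genes called. Small changes, and most interactions, are thus beyond these libraries. Signs of the median, the mean and camera differed for 5, 3, 5, 2, 3 and 4 lists in that order. Under upper-quartile scaling the sign of the list median turned for unfolded protein genes in Cdx2 KO against WT, tuft cell and oxidative phosphorylation genes in Eed KO against WT, and PRC2 subunits, lipid, Paneth cell and unfolded protein genes in DKO against WT. It also turned for T cell genes in DKO against Eed KO and for PRC1 subunits, iron and stroma genes in the interaction. Under relative log expression it turned for PRC1 subunits in Cdx2 KO against WT and oxidative phosphorylation genes in DKO against Eed KO. Counts of 3 or fewer called members of a list often fell to 0, or moved more than 1.5-fold, with 1 library left out.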

Results

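RNA was sequenced from villus epithelium of the mouse jejunum, and reads were counted per gene. The 9 libraries fell into 4 groups by their labels: WT (n = 2), Cdx2 KO (n = 3), Eed KO (n = 2) and DKO, with both genes targeted (n = 2). CDX2 is a transcription factor of the intestinal epithelium. EED is a subunit of polycomb repressive complex 2 (PRC2), which methylates histone H3 at lysine 27 and keeps developmental genes silent. Total counts were 30678310 and 18025952 in the WT libraries, 19480191, 20959839 and 26447163 in Cdx2 KO, 15727147 and 23934061 in Eed KO, and 31737648 and 20014643 in DKO. The series holds 38 further samples, of chromatin assays, which were not analysed here. Knockout mice carried Villin-cre and received 1 mg tamoxifen on each of 5 days and were killed 3 days after the last dose, while WT mice received oil and had no Cre. Tamoxifen and Cre therefore differ in every comparison with WT, and do not differ in DKO against Cdx2 KO or against Eed KO. Log2 fold changes are given ± SE from edgeR, and levels as mean CPM ± SD, where CPM are counts scaled to the same library size.

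Reads over Eed fell and reads over Cdx2 did not fall in the libraries labelled as knockouts of the gene concerned. Eed was 24.0 ± 1.52 CPM in WT, 25.0 ± 4.16 in Cdx2 KO, 6.53 ± 0.212 in Eed KO and 6.61 ± 0.347 in DKO. It fell by 1.88 ± 0.21 on the log2 scale in Eed KO and 1.86 ± 0.21 in DKO against WT (adjusted p = 0.00777 and 0.000898). Cdx2 was 183 ± 1.02 CPM in WT, 286 ± 12.5 in Cdx2 KO, 109 ± 8.89 in Eed KO and 266 ± 39.4 in DKO. It rose by 0.65 ± 0.17 in the libraries labelled Cdx2 KO (adjusted p = 0.0219) and fell by 0.74 ± 0.18 in Eed KO (adjusted p = 0.036). In DKO against WT the Cdx2 value was 0.54 ± 0.18 (adjusted p = 0.0553). In each case every library of the first group lay outside the range of WT. The labels do not say which exons were floxed, and reads from the rest of the transcript were counted too. Cdx2 reads thus go against the label, and by themselves they cannot check that CDX2 was lost. Genes known from the literature as CDX2 targets went with the label. In Cdx2 KO against WT 12 of them fell and 2 rose, with a median of -1.33. In DKO against Eed KO 8 fell and 1 rose, with a median of -0.98. For these targets the values argue against a label whose direction is wrong. They do not measure CDX2 itself, so its loss still rests on the labels. Eed reads went with the label in DKO against Cdx2 KO too (-1.92 ± 0.20, adjusted p = 0.0115).

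**Figure D1:**
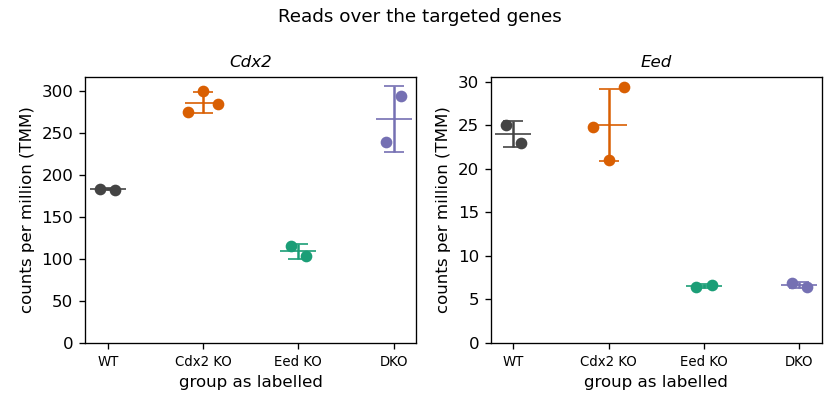
Reads over Cdx2 (left) and Eed (right) in each library, in TMM-scaled CPM, by group as labelled; points are libraries, and bars show the mean and SD. Cdx2 was 183 CPM in WT and 286 in Cdx2 KO, while Eed was 24.0 in WT and 6.53 in Eed KO.

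The first principal component of the 1000 most variable genes held 66.5% of their variance and the second 16.1%. Spearman correlations across genes were 0.961 to 0.988 within groups and 0.849 to 0.968 between groups. Sex-linked genes split the libraries in another way. Xist, the RNA that coats the inactive X chromosome, was at 497, 0.146 and 563 CPM in Cdx2 KO replicates 1, 2 and 3 and at 359 and 278 in DKO, and below 0.5 in the WT and Eed KO libraries. The Y-linked gene Ddx3y was at 63.5 and 67.1 CPM in WT and 15.4 and 28.0 in Eed KO. It was at 0.0460, 40.5 and 0.187 in Cdx2 KO replicates 1, 2 and 3, and at 0.0304 and 0 in DKO. This split goes with the group in DKO against WT and DKO against Eed KO, and cannot be separated from it there. In Cdx2 KO against WT and DKO against Cdx2 KO it goes with the group in part, since Cdx2 KO replicate 2 resembled WT. Of the 5 sex-linked genes, Xist rose in Cdx2 KO, DKO against WT and DKO against Eed KO, and Ddx3y fell in DKO against WT (1 rose and 0 fell in Cdx2 KO, and 1 rose and 4 fell in each DKO comparison named, adjusted over the list alone). Xist was no longer called in Cdx2 KO without WT replicate 1, WT replicate 2 or Cdx2 KO replicate 3. It was not called in DKO against WT without any WT or DKO library, nor in DKO against Eed KO without any library but Cdx2 KO replicate 2.

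The libraries labelled Cdx2 KO were compared with WT to ask which genes need CDX2 in adult villus cells. Sis, which encodes the brush border enzyme that splits sucrose, fell from 11489 ± 5933 to 174 ± 62.7 CPM, a change of -6.04 ± 0.51 (adjusted p = 0.000206). Enpp7, the alkaline sphingomyelinase of the brush border, changed by -9.84 ± 0.70, and Fabp6, the ileal bile acid-binding protein, by -10.01 ± 0.58. Sult1c2, a sulfotransferase of gastric epithelium, rose from 0.343 ± 0.0244 to 295 ± 80.6 CPM (9.74 ± 0.52, adjusted p = 3.25e-05). Ctse, the gastric protease cathepsin E, rose by 5.59 ± 0.41. Cdx2 reads were higher in these libraries, against their label. Of 13181 genes tested, 2022 rose and 1865 fell, 1617 and 1159 of them at least 2-fold. With upper-quartile scaling 2511 rose and 1499 fell, 62.6% higher in place of 52.0%, and the median of all genes moved by 0.155. The calls were 742 and 957 with WT replicate 1 left out, 496 and 903 with WT replicate 2 left out, 1117 higher with Cdx2 KO replicate 1 left out and 1306 higher with Cdx2 KO replicate 3 left out.

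Of 21 tested brush border digestion genes, 16 fell in Cdx2 KO and none rose (17 and none adjusted over the list alone), with a median of -2.62 (camera, adjusted p = 4.87e-12, and adjusted p = 0.358 with an estimated correlation). They included Mep1a, a meprin metalloprotease (-5.91 ± 0.63), and Xpnpep2, an aminopeptidase (-4.10 ± 0.56). Among 18 sugar, amino acid and peptide transporters 8 fell (10 adjusted over the list alone), such as the nucleoside transporter Slc28a1 (-6.40 ± 0.63) and the proline transporter Slc6a20a (-3.73 ± 0.24), with adjusted p = 4.29e-06, and adjusted p = 0.449 with an estimated correlation. In the list of 23 xenobiotic metabolism genes 11 fell and 2 rose (11 and 2 adjusted over the list alone; adjusted p = 0.000136, and adjusted p = 0.446 with an estimated correlation). The efflux pump gene Abcb1a (-5.85 ± 0.49) and the cytochrome P450 gene Cyp2j6 (-3.83 ± 0.21) fell, while the glutathione transferase gene Gsta4 rose (4.01 ± 0.30). Of 23 lipid absorption genes 5 fell and 1 rose (5 and 1 adjusted over the list alone), at adjusted p = 0.00199, and adjusted p = 0.724 with an estimated correlation. The cholesterol exporter Abca1 (-5.47 ± 0.33) and the fatty acid translocase Cd36 (-4.90 ± 0.60) fell and the lipoprotein receptor Scarb1 rose (3.48 ± 0.30). Leaving out WT replicate 1 or 2 left 5 transport genes falling in either case, leaving out WT replicate 2 left 7 xenobiotic genes falling, and leaving out Cdx2 KO replicate 2 gave 9 lipid genes.

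Of 19 tested genes known from the literature as CDX2 targets, 12 fell and 2 rose in Cdx2 KO (12 and 2 adjusted over the list alone), with a median of -1.33 (adjusted p = 2.14e-06, and adjusted p = 0.358 with an estimated correlation). Those that fell included Hnf4g, a nuclear receptor of enterocytes (-2.46 ± 0.24), Isx, an intestine-specific homeobox gene (-3.36 ± 0.55), and Vdr, the vitamin D receptor (-2.16 ± 0.19). Among 29 intestinal transcription factors 7 fell and 4 rose, as they did adjusted over the list alone (camera, adjusted p = 0.258), with Foxa2 (2.14 ± 0.41), a regulator of foregut endoderm, among those that rose. Of 9 ileal bile acid and vitamin B12 uptake genes 6 fell (7 adjusted over the list alone), with a median of -2.52 (adjusted p = 0.00025, and adjusted p = 0.358 with an estimated correlation), Cubn, the vitamin B12 receptor cubilin, by -2.90 ± 0.57. A WT piece taken nearer the ileum would also lower these genes and Fabp6 here, and cannot be told apart from Cdx2 loss in this comparison. In DKO against Eed KO, which holds no WT library, 3 of them fell and 0 rose, with a median of -1.46. Against the WT mean their median was -0.15 and -1.19 in the Eed KO libraries and -2.45 and -2.31 in DKO. Hardly any of them were called there with an Eed KO or DKO library left out, which leaves 1 library in that group. Of 15 iron, calcium and vitamin D transport genes 5 fell and 2 rose (6 and 3 adjusted over the list alone; camera, adjusted p = 0.0544), and Cybrd1, a duodenal iron reductase, rose by 4.43 ± 1.08. With WT replicate 1 left out 7 CDX2 targets fell, and with WT replicate 2 left out 7 CDX2 targets and 3 ileal genes fell; 4 transcription factors fell in both cases, and 1 rose in the second. Iron and calcium genes fell in 3 cases without WT replicate 2 and 3 without Cdx2 KO replicate 1, and none rose without WT replicate 1.

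Of 19 tested stomach and foregut genes, 14 rose in Cdx2 KO and none fell (16 and none adjusted over the list alone), with a median of 8.18, or 7.38 with genes absent from WT at their lower bound (camera, adjusted p = 3.18e-15, and adjusted p = 0.258 with an estimated correlation). The gastrokine Gkn3 (8.18 ± 0.81) and the annexin Anxa10 (8.10 ± 0.79) rose. Pgc, the precursor of the gastric protease pepsin C, was at least 396-fold higher, the water channel Aqp5 at least 172-fold higher and the adhesion gene Vsig1 at least 160.4-fold higher, since all WT libraries had 0 reads for each. These bounds are set against 3 counts over the libraries of the group at 0, and like the intervals they cover counting error only. Of the 19 tested genes 5 had 0 counts in WT or in Cdx2 KO. Genes silent in WT passed the filter on low counts only through other groups, and they could rise but not fall here. The count of rising genes, with none falling, is thus partly set by the filter. Ly6d (11.25 ± 0.74), a surface antigen of squamous and foregut cells, and Lyve1 (7.41 ± 0.39), best known from lymphatic endothelium, also rose. Outside the fixed lists, Cyp2d34 was at least 517-fold and Cyp2d9 at least 328-fold higher, in a family of near-identical genes whose reads may be shared. H19, an imprinted fetal RNA, had a ratio of 11425 (95% counting interval 2050.3 to 451284), Mfi2, an iron-binding membrane protein, of 7459 (95% counting interval 2065 to 61598) and Lcn2, an iron-sequestering antimicrobial protein, of 1617 (95% counting interval 553 to 7844). In the fetal and injury-associated list 10 of 21 rose and 3 fell (11 and 4 adjusted over the list alone; camera, adjusted p = 0.0668), with Anxa3 (4.01 ± 0.61) and Krt7 (3.57 ± 0.54) rising. That list had 3 rising genes without WT replicate 1 and 3 without WT replicate 2.

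Markers of secretory cells moved apart in Cdx2 KO. Of 17 tested goblet cell genes 10 rose and none fell (11 and none adjusted over the list alone), with Spink4 at 2.63 ± 0.28 and Ccl9 at 4.48 ± 0.68 (adjusted p = 6.8e-05, and adjusted p = 0.426 with an estimated correlation). Of 20 enteroendocrine genes 10 fell and none rose (11 and none adjusted over the list alone), with the incretin hormone gene Gip at -2.85 ± 0.24 and neurotensin, Nts, at -4.71 ± 0.60 (adjusted p = 6.8e-05, and adjusted p = 0.724 with an estimated correlation). Of 13 tuft cell genes 4 rose (9 rose and 1 fell adjusted over the list alone), at adjusted p = 0.0224, and adjusted p = 0.724 with an estimated correlation. They included the marker kinase Dclk1 (1.93 ± 0.50) and the tuft cell regulator Pou2f3 (1.61 ± 0.49). Paneth cell genes gave 2 rising of 15 tested, Mmp7 and Habp2, also adjusted over the list alone (camera, adjusted p = 0.258). Defensin genes in that list are near-identical and share reads. Goblet genes rose in 4 cases without WT replicate 2. Enteroendocrine genes fell in 4, 5 and 4 cases when WT replicate 1, WT replicate 2 or Cdx2 KO replicate 1 was left out. Tuft genes rose in 0, 1, 2 and 2 cases without WT replicate 1, WT replicate 2, Cdx2 KO replicate 1 or replicate 3, and no Paneth gene rose without either WT library.

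Genes of the crypt and of cell division also rose in Cdx2 KO, unevenly between its libraries. Of 17 crypt stem cell genes 8 rose (12 adjusted over the list alone), with Ephb3 at 3.19 ± 0.84 and the growth brake Lrig1 at 1.84 ± 0.43 (adjusted p = 0.012, and adjusted p = 0.724 with an estimated correlation). Of 26 proliferation genes 9 rose (11 adjusted over the list alone), with the replication helicase genes Mcm2 at 2.14 ± 0.32 and Mcm6 at 2.94 ± 0.68 (adjusted p = 6.87e-05, and adjusted p = 0.724 with an estimated correlation). The median crypt stem difference from WT was 1.82, 1.22 and 2.80 in Cdx2 KO replicates 1, 2 and 3, and the Paneth median was -0.37, 0.09 and 2.58. Rising crypt genes numbered 1, 0, 3 and 2 without WT replicate 1, WT replicate 2, Cdx2 KO replicate 1 or replicate 3, and proliferation genes 3, 1, 4 and 6.

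In the interferon and MHC list of 26 genes, 12 rose and 5 fell in Cdx2 KO (16 and 7 adjusted over the list alone), at adjusted p = 0.0247, and adjusted p = 0.724 with an estimated correlation. The interferon-induced GTPases Gbp2 (4.28 ± 0.42) and Irgm1 (3.36 ± 0.34) rose, while the MHC class II gene H2-Aa (-3.18 ± 0.77) and its activator Ciita (-2.31 ± 0.50) fell. Of 18 cholesterol synthesis genes 7 rose and 1 fell (11 and 1 adjusted over the list alone), with Mvd at 2.11 ± 0.52 and Insig1 at 1.95 ± 0.50 (adjusted p = 0.00437, and adjusted p = 0.724 with an estimated correlation). Of 30 oxidative phosphorylation genes 5 fell (0 adjusted over the list alone), with a median of -0.37 (adjusted p = 0.02, and adjusted p = 0.75 with an estimated correlation). Of 19 fatty acid oxidation genes 9 fell and 2 rose (9 and 4 adjusted over the list alone; camera, adjusted p = 0.0522), and the ketogenic enzyme gene Hmgcs2 rose by 4.62 ± 1.00. Of 17 antimicrobial and acute-phase genes 4 fell and 3 rose (4 and 6 adjusted over the list alone; camera, adjusted p = 0.891), with the lectin gene Reg3a at -8.55 ± 0.97. Interferon and MHC genes rose in 4 cases and fell in 1 without WT replicate 1. Cholesterol genes rose in 11 cases without WT replicate 1 and in 0, 2 and 2 without WT replicate 2, Cdx2 KO replicate 1 or replicate 2. Leaving out either Eed KO library gave 4 and either DKO library 3. Oxidative phosphorylation genes fell in 1, 0, 0 and 1 cases without WT replicate 1, WT replicate 2, Cdx2 KO replicate 1 or replicate 3, and in 8 without Cdx2 KO replicate 2. Fatty acid genes fell in 4, 4 and 5 cases without WT replicate 1, WT replicate 2 or Cdx2 KO replicate 1. Antimicrobial genes fell in 1 case and rose in 0 without either WT library, and fell in 2, 1, 2 and 2 without Cdx2 KO replicate 1, Cdx2 KO replicate 3 or either DKO library.

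Of 6 stroma, muscle and endothelium genes Lyve1 and S100b rose in Cdx2 KO, also adjusted over the list alone (camera, adjusted p = 0.0224, and adjusted p = 0.358 with an estimated correlation), and 1 rose without either WT library. Of the pancreas and blood genes Ctrb1, a pancreatic chymotrypsinogen, was the 1 with enough counts to test, and it had a ratio of 1026 (95% counting interval 184 to 40536), also when adjusted over the list alone. No T cell gene was called by edgeR in either adjustment, at an unadjusted p under 0.05 or by DESeq2 (0 in each), but Cdx2 KO replicate 2 stood apart at -2.56, against 0.02 and 0.28 in replicates 1 and 3, and 1 fell without replicate 3. Of 11 B cell and myeloid genes Pou2af1 rose (1 adjusted over the list alone; camera, adjusted p = 0.901). p53 targets gave 3 rising and 2 falling of 18 (6 and 3 adjusted over the list alone; camera, adjusted p = 0.994). PRC2 subunits gave 3 rising and 1 falling of 12 (3 and 1 adjusted over the list alone; camera, adjusted p = 0.605), with the histone-binding subunit gene Rbbp7 at 1.59 ± 0.24. Unfolded protein and integrated stress genes gave 3 rising and 3 falling of 19 (4 and 4 adjusted over the list alone; camera, adjusted p = 0.891). Heat shock and immediate early genes gave 1 and 1 of 16 (1 and 1 adjusted over the list alone; camera, adjusted p = 0.768). p53 targets rose in 1 and 0 cases without WT replicate 1 or 2 and in 6 without either Eed KO library, and 1 fell without any WT or Cdx2 KO library. PRC2 subunits rose in 1 case without WT replicate 1, WT replicate 2, Cdx2 KO replicate 1 or replicate 3, and none fell without WT replicate 2. No B cell or myeloid gene rose without either WT library. Unfolded protein genes rose in 1 case without WT replicate 1, WT replicate 2 or Cdx2 KO replicate 3, and 1 fell without either WT library. No heat shock gene fell without WT replicate 1, WT replicate 2 or Cdx2 KO replicate 1, and 3 rose and 2 fell without either DKO library. Without Cdx2 KO replicate 2, whose Xist and Y-linked reads resembled WT, 14 CDX2 targets fell and 11 crypt stem genes rose.

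**Figure D2:**
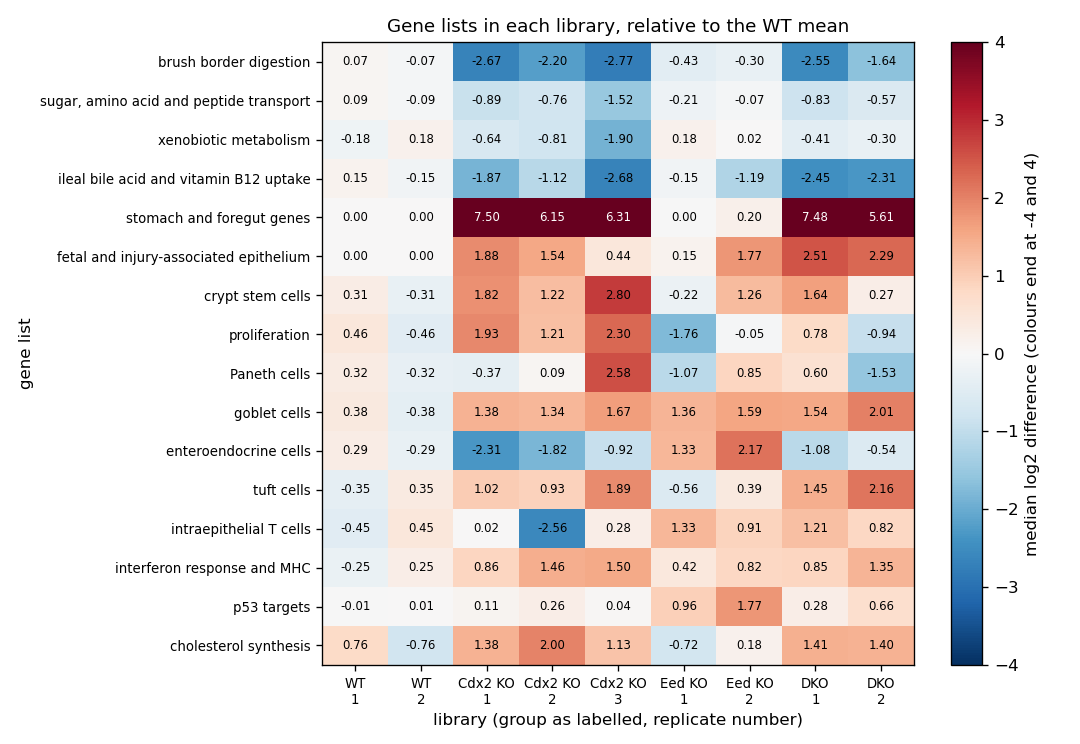
Median log2 difference from the WT mean over the tested members of 16 gene lists (vertical axis) in each of the 9 libraries (horizontal axis, group as labelled and replicate number); colours end at -4 and 4. Stomach genes stood at 7.50, 6.15 and 6.31 in the Cdx2 KO libraries and at 0.00 and 0.20 in the Eed KO libraries.

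DKO was compared with Eed KO to ask for the effect of CDX2 loss where PRC2 is also impaired; both groups had tamoxifen and Cre, and neither is in the comparison of Cdx2 KO with WT. Sis was 4989 ± 2104 CPM in Eed KO and 76.1 ± 17.5 in DKO (-6.04 ± 0.61, adjusted p = 0.000921), and Enpp7 changed by -7.36 ± 0.76. Sult1c2 rose by 7.96 ± 0.47 and Ctse by 5.79 ± 0.39, and the complement regulator Cfh by 10.94 ± 0.90. The gastric tight junction gene Cldn18 was at least 295-fold higher, Vsig1 at least 141-fold higher and the fibrinogen gene Fga at least 265-fold higher, with 0 reads in Eed KO. The gastrokine Gkn2 had a ratio of 5582 (95% counting interval 1002 to 220521) and the trefoil factor Tff2 of 5063 (95% counting interval 908 to 200014). Among genes that fell were Slc5a8, a monocarboxylate transporter (-8.03 ± 0.61), Plb1, a brush border phospholipase (-7.19 ± 0.70), and the adenosine receptor Adora2b, with a ratio of 865 (95% counting interval 239 to 7148) in favour of Eed KO. In edgeR 650 genes rose and 804 fell, 560 and 677 at least 2-fold. The calls were 399 higher without Cdx2 KO replicate 1, 213 and 337 without Eed KO replicate 1, 400 and 532 without Eed KO replicate 2, 290 and 240 without DKO replicate 1 and 374 and 402 without DKO replicate 2.

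Stomach genes rose in 13 of 19 cases in DKO against Eed KO and none fell (16 and none adjusted over the list alone), with a median of 7.71, or 5.79 at the bounds (camera, adjusted p = 9.71e-20, and adjusted p = 0.194 with an estimated correlation). Of these genes 5 had 0 counts in Eed KO or in DKO, so the filter on low counts bears on this count as well. Brush border genes fell in 8 of 21 cases (12 fell and 2 rose adjusted over the list alone; adjusted p = 4.91e-07, and adjusted p = 0.665 with an estimated correlation). CDX2 targets fell in 8 and rose in 1 of 19 (10 and 3 adjusted over the list alone; adjusted p = 7.87e-06, and adjusted p = 0.453 with an estimated correlation). Enteroendocrine genes fell in 14 of 20 cases (19 adjusted over the list alone), with Gip at -3.92 ± 0.28, Nts at -6.20 ± 0.76 and the endocrine regulator Pax6 at -4.20 ± 0.79 (adjusted p = 5.32e-14, and adjusted p = 0.453 with an estimated correlation). Tuft cell genes rose in 6 of 13 cases (12 rose and 1 fell adjusted over the list alone), Dclk1 by 2.35 ± 0.54 (adjusted p = 2.43e-05, and adjusted p = 0.807 with an estimated correlation). Cholesterol synthesis genes rose in 5 of 18 cases (14 adjusted over the list alone), Insig1 by 2.44 ± 0.53 (adjusted p = 7.87e-06, and adjusted p = 0.827 with an estimated correlation). With Eed KO replicate 1, Eed KO replicate 2, DKO replicate 1 or DKO replicate 2 left out, stomach genes rose in 8, 8, 12 and 13 cases, brush border genes fell in 4, 4, 2 and 8, and CDX2 targets in 5, 6, 3 and 5. In the same order enteroendocrine genes fell in 8, 3, 3 and 4 cases, tuft genes rose in 0, 4, 0 and 0 and cholesterol genes in 0, 1, 0 and 0. Without WT replicate 1, WT replicate 2 or Cdx2 KO replicate 1, enteroendocrine genes fell in 9, 10 and 12 cases, tuft genes rose in 4, 4 and 1 and cholesterol genes in 10, 10 and 2.

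p53 target genes fell in DKO against Eed KO in 8 of 18 cases (10 adjusted over the list alone), among them the cell death gene Bax (-1.48 ± 0.21), Phlda3 (-3.22 ± 0.57) and Plk2 (-1.78 ± 0.40), with adjusted p = 3.09e-06, and adjusted p = 0.453 with an estimated correlation. Proliferation genes gave 2 rising of 26, Rrm2 and Tk1, as adjusted over the list alone (adjusted p = 0.0338, and adjusted p = 0.833 with an estimated correlation). The stroma, muscle and endothelium list had 2 rising of 6 tested, Lyve1 (7.49 ± 0.40) and S100b, also adjusted over the list alone (adjusted p = 0.0016, and adjusted p = 0.236 with an estimated correlation). Sugar and amino acid transport genes fell in 2 of 18 cases (3 adjusted over the list alone; adjusted p = 0.0216, and adjusted p = 0.833 with an estimated correlation). Lipid genes fell in 4 and rose in 1 of 23 (5 and 1 adjusted over the list alone; adjusted p = 0.0278, and adjusted p = 0.833 with an estimated correlation). p53 targets fell in 3, 2 and 5 cases without Eed KO replicate 2, DKO replicate 1 or DKO replicate 2, and proliferation genes rose in 0, 1 and 0 without Eed KO replicate 1, Eed KO replicate 2 or DKO replicate 1. Transport genes fell in 4 cases without Cdx2 KO replicate 3.

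The effect of the Cdx2 label was similar in direction with and without Eed. Over the 3887 genes called in Cdx2 KO against WT, 3619 (93.1%) had the same sign in DKO against Eed KO, and the slope through 0 was 0.642 with a jackknife SE over libraries of 0.123. Across these genes, which are not independent replicates, Pearson's r was 0.874 and Spearman's rho 0.878. Over all 13181 genes the slope was 0.632 and 74.5% shared a sign. Error in the Cdx2 KO changes pulls both slopes toward 0, and picking genes by those changes adds to this in the first. They thus do not measure a weaker Cdx2 effect without Eed. Over the 1454 genes called in DKO against Eed KO, the slope of the Cdx2 KO change on the DKO change was 0.922, with 95.8% sharing a sign. Of the genes that fell in Cdx2 KO, 631 also fell in DKO against Eed KO, where 113.8 would be shared by independent draws, and 483 rose in both, against 99.7. These comparisons share no library. In both, however, the libraries with Xist reads lay in the group with the Cdx2 label, all of DKO and all of Cdx2 KO but replicate 2. A difference tied to sex could thus run through both. Fabp6 changed by -10.01 ± 0.58 in the first and -2.58 ± 0.64 in the second, having been low already in Eed KO.

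**Figure D3:**
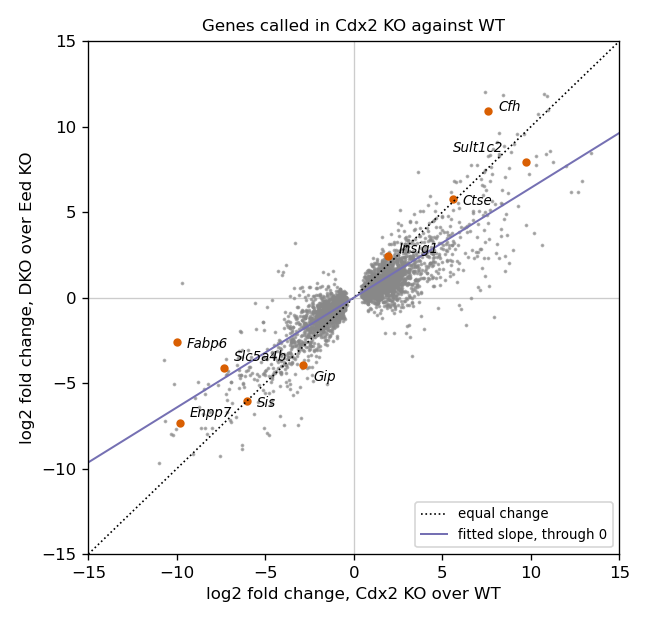
Log2 fold change in DKO over Eed KO (vertical) against that in Cdx2 KO over WT (horizontal) for the 3887 genes called in Cdx2 KO against WT; each grey point is a gene, orange points are named, the dotted line marks equal change and the solid line the fitted slope of 0.642. Sis lies on the dotted line at -6.04 and -6.04, and Gip at -2.85 and -3.92.

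Eed KO was compared with WT to ask which genes PRC2 keeps silent, or on, in villus cells with Cdx2 intact. The cell cycle inhibitor gene Cdkn2a rose from 0.175 ± 0.162 to 79.5 ± 17.2 CPM (8.62 ± 0.50, adjusted p = 0.000804), and it was at 26.7 ± 1.06 CPM in DKO. Genes near silence in WT villus appeared. The homeobox gene Hoxb13 had a ratio of 1028 (95% counting interval 184 to 40649.9) and the enamel and kidney gene Wdr72 of 1007 (95% counting interval 180.3 to 39836). For the zinc finger gene Zbtb16 it was 481 (95% counting interval 164 to 2337), and the growth factor gene Bmp4 was at least 132-fold higher. Phlda3, a p53-induced inhibitor of AKT, rose by 8.04 ± 0.80. Fabp6 fell from 895 ± 316 CPM in WT to 2.37 ± 0.279 in Eed KO (-8.57 ± 0.65, adjusted p = 0.00301). Lower too were the phospholipase genes Pla2g4c at -7.42 ± 0.81 and Plb1 at -3.81 ± 0.53, and the bile acid transporter Slc10a2 at -4.88 ± 1.24. In edgeR 532 genes rose and 844 fell, 453 and 476 at least 2-fold. Upper-quartile scaling gave 697 and 510, 57.7% higher in place of 38.7%, with the median of all genes moved by 0.145, so the split between higher and lower turned. The calls fell to 291 and 346 without Cdx2 KO replicate 1, which is not in this comparison. Leaving out a WT or Eed KO library lowered them further, and without WT replicate 1 almost none remained. Each of these fits holds 1 library in the group concerned, so lost power cannot be told apart from a pattern carried by 1 library. No gene called with all libraries turned its sign in these fits.

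p53 target genes rose in Eed KO in 9 of 18 cases and none fell (11 and none adjusted over the list alone), with a median of 1.47 (camera, adjusted p = 2.01e-10, and adjusted p = 0.306 with an estimated correlation). Bax rose by 1.72 ± 0.21, Plk2 by 3.67 ± 0.43 and the death receptor gene Eda2r had a ratio of 161 (95% counting interval 54.6 to 782). Of 6 tested CDK inhibitors Cdkn2a rose and Cdkn1b fell (-0.98 ± 0.18), or 2 and 1 adjusted over the list alone (adjusted p = 0.00916, and adjusted p = 0.306 with an estimated correlation). Of 11 tested developmental regulators that are textbook PRC2 targets, 3 rose and 1 fell (5 and 1 adjusted over the list alone), with Meis2 at 4.33 ± 0.71, Pax6 at 3.50 ± 0.75 and Otx1 at least 23.6-fold higher (adjusted p = 0.0157, and adjusted p = 0.588 with an estimated correlation). That list has 77 members in the table and the Hox list 39, of which 1, Hoxb13, had enough counts to be tested; it rose, and did so adjusted over the list alone. PRC2 subunits gave 1 rising and 2 falling of 12 (2 and 6 adjusted over the list alone; camera, adjusted p = 0.0677), with Suz12, the partner of EED, at -1.32 ± 0.23. PRC1 subunits gave 2 rising and 2 falling of 19 (5 and 5 adjusted over the list alone; camera, adjusted p = 0.659). p53 targets rose in 0, 3 and 6 cases without WT replicate 1, WT replicate 2 or Eed KO replicate 2. Developmental genes rose in 0, 0, 2 and 1 cases without WT replicate 1, WT replicate 2, Eed KO replicate 1 or Eed KO replicate 2, and Cdkn2a rose in every case. Hoxb13 was no longer called without WT replicate 1, WT replicate 2 or Eed KO replicate 2. PRC2 subunits rose in 0 cases without any library but Cdx2 KO replicate 2 or 3, and fell in 0, 1 and 1 without WT replicate 1, WT replicate 2 or Eed KO replicate 1. No PRC1 subunit was called without WT replicate 1, WT replicate 2, Cdx2 KO replicate 1 or Eed KO replicate 1, and 1, falling, without Eed KO replicate 2.

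Goblet and enteroendocrine genes rose in Eed KO. Goblet cell genes rose in 11 of 17 cases and none fell (12 and none adjusted over the list alone) (camera, adjusted p = 7.75e-09, and adjusted p = 0.306 with an estimated correlation). The lectin gene Zg16 went from 1488 ± 516 to 6282 ± 1307 CPM (2.08 ± 0.41), and Sytl2 changed by 1.65 ± 0.32. Enteroendocrine genes rose in 6 of 20 cases and none fell (12 and none adjusted over the list alone), among them Gip (2.73 ± 0.27), the ghrelin gene Ghrl (3.51 ± 0.51) and cholecystokinin, Cck (2.22 ± 0.35), with adjusted p = 1.89e-09, and adjusted p = 0.588 with an estimated correlation. In edgeR 0 of 15 Paneth cell genes and 0 of 13 tuft cell genes were called, by the adjustment over all genes or over the list alone, with medians of 0.26 and -0.04. The 2 Eed KO libraries stood apart, at -1.07 and 0.85 for Paneth and -0.56 and 0.39 for tuft genes, and the medians ran from -1.98 to 0.82 and from -0.61 to 0.37 with 1 library left out, where 1 tuft gene rose without Cdx2 KO replicate 3. Unadjusted p was under 0.05 for 0 Paneth and 1 tuft gene, which was higher, and DESeq2 called 0 and 1. Fetal and injury-associated genes rose in 4 of 21 cases (7 rose and 1 fell adjusted over the list alone), with Clu at 3.61 ± 0.69, the alpha-fetoprotein gene Afp at 3.18 ± 0.79 and Igf2bp3 at 4.68 ± 0.79 (adjusted p = 0.0024, and adjusted p = 0.764 with an estimated correlation). Stomach genes rose in 2 of 19 cases, Ctse and Capn9 (4 adjusted over the list alone), with a median of 0.14 (adjusted p = 0.041, and adjusted p = 0.822 with an estimated correlation). The median was 1.45 with 1 member set at its bound and 6 members left out that had 3 counts or fewer in both groups. Without WT replicate 1 or WT replicate 2, no goblet, fetal or stomach gene rose, and 0 and 1 enteroendocrine genes did. Goblet genes rose in 5, 1 and 0 cases, enteroendocrine genes in 5, 4 and 3, and fetal genes in 3, 2 and 1 without Cdx2 KO replicate 1, Eed KO replicate 1 or Eed KO replicate 2. Stomach genes rose in 2, 0 and 0 of those cases, and in 4 without Cdx2 KO replicate 3.

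Of the 9 ileal uptake genes 2 fell in Eed KO, Fabp6 and Slc10a2 (3 fell and 1 rose adjusted over the list alone), with a median of -0.98 (adjusted p = 0.0104, and adjusted p = 0.588 with an estimated correlation). Lipid absorption genes gave 1 rising and 0 falling of 23 (1 and 0 adjusted over the list alone; camera, adjusted p = 0.0887), with a median of 0.39. Fatty acid oxidation genes rose in 3 of 19 cases (6 adjusted over the list alone), with Hmgcs2 at 5.44 ± 1.06 (adjusted p = 0.0157, and adjusted p = 0.764 with an estimated correlation). Interferon and MHC genes rose in 2 of 26 cases, Gbp2 and Nlrc5 (1 adjusted over the list alone; adjusted p = 0.00572, and adjusted p = 0.838 with an estimated correlation). No brush border gene was called in edgeR, by the adjustment over all genes or over the list alone (0 higher and 5 lower at an unadjusted p under 0.05, 0 and 3 in DESeq2), with a median of -0.49 (adjusted p = 0.041, and adjusted p = 0.917 with an estimated correlation). The same was so for the 18 intraepithelial T cell genes (0 at an unadjusted p under 0.05 and 0 in DESeq2), with a median of 1.05 (adjusted p = 0.041, and adjusted p = 0.917 with an estimated correlation). Unfolded protein and integrated stress genes went both ways, 2 rising and 2 falling of 19 (2 and 4 adjusted over the list alone; camera, adjusted p = 0.559), with the chaperone gene Hspa5 at -0.99 ± 0.24. Heat shock and immediate early genes gave 1 rising and 1 falling of 16 (3 and 1 adjusted over the list alone; camera, adjusted p = 0.599), with the chaperone gene Hsph1 at -2.13 ± 0.52. All these counts were 0 without WT replicate 1 except Fabp6, which fell, and 0 without WT replicate 2 except Fabp6 again and 1 rising lipid gene. Fatty acid genes rose in 0 cases without Eed KO replicate 1 and 6 without Cdx2 KO replicate 3. Brush border genes fell in 1 and 2 cases without Cdx2 KO replicate 2 or 3, with medians of -0.61 to -0.19 over all libraries left out in turn, and 2 T cell genes rose without Cdx2 KO replicate 2. Interferon genes rose in 0 cases without Eed KO replicate 2 and 1 without Cdx2 KO replicate 1, Cdx2 KO replicate 2 or either DKO library. Ileal genes fell in 1 case without either Eed KO library. Unfolded protein genes gave 1 rising and 0 falling without Eed KO replicate 1, 1 and 1 without Cdx2 KO replicate 1, and 0 without Eed KO replicate 2. No heat shock gene was called without Cdx2 KO replicate 1 or Eed KO replicate 2, 2 rose and 0 fell without Eed KO replicate 1, and 3 fell without either DKO library.

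DKO was compared with Cdx2 KO to ask which genes change when PRC2 is impaired in cells labelled as lacking CDX2; both groups had tamoxifen and Cre. Cdkn2a rose most plainly, from 0.0361 ± 0.0323 CPM to 26.7 ± 1.06, a ratio of 657 (95% counting interval 224 to 3192) (adjusted p = 0.000351). Hddc3 (5.08 ± 0.37), Ndrg4 (4.94 ± 0.73) and the proapoptotic gene Plekhf1 (3.92 ± 0.51) rose, and Wdr72 was at least 397-fold higher. The drug-metabolising gene Cyp3a11 rose from 489.5 ± 275 to 3758 ± 495 CPM (2.94 ± 0.55, adjusted p = 0.0289), and the uroguanylin gene Guca2b changed by 2.40 ± 0.53. Genes that fell included the transferrin receptor Tfrc (-3.28 ± 0.74), the chaperone Hsph1 (-2.59 ± 0.50) and the interleukin 1 antagonist Il1rn (-2.95 ± 0.51). In edgeR 432 genes rose and 520 fell, 328 and 266 at least 2-fold. DESeq2 called 1122 and 1308, but edgeR called 8 and 3 when the fit held these 5 libraries alone. The calls were 14 and 4, 733 and 861, and 90 and 36 without Cdx2 KO replicate 1, 2 or 3. They were 205 and 100 without DKO replicate 1, 6 and 0 without DKO replicate 2, 120 and 86 without WT replicate 1 and 102 and 51 without WT replicate 2.

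Proliferation genes had a median of -1.58 in DKO against Cdx2 KO, though 1 of 26, Tyms, fell by itself (-1.06 ± 0.26; 5 fell adjusted over the list alone), with adjusted p = 2.1e-06, and adjusted p = 0.686 with an estimated correlation. That median ranged from -2.63 to -0.97 with 1 library left out. In edgeR 0 of 17 crypt stem and 0 of 15 Paneth genes were called in either adjustment (0 higher and 2 lower, and 0 and 1, at an unadjusted p under 0.05; 0 and 0 in DESeq2). Their medians were -0.93 and -1.28 (camera, adjusted p = 0.0981 and 0.852), and Paneth genes stood at 2.58 in Cdx2 KO replicate 3, apart from the others. No T cell gene was called in edgeR in either adjustment (6 higher at an unadjusted p under 0.05, 2 in DESeq2), with a median of 1.28 (adjusted p = 0.000179, and adjusted p = 0.686 with an estimated correlation). They stood at -2.56 in Cdx2 KO replicate 2 and 0.02 and 0.28 in replicates 1 and 3. Lists of enterocyte function were higher by camera, each with adjusted p = 0.686 with an estimated correlation. Lipid genes had 2 of 23 rising (4 adjusted over the list alone; adjusted p = 0.000538) and xenobiotic genes 2 of 23 (3 over the list alone; adjusted p = 0.000831). Fatty acid oxidation genes had 2 of 19 rising (3 over the list alone; adjusted p = 0.000654), and iron and calcium genes 2 rising and 1 falling of 15 (5 and 1 over the list alone; adjusted p = 0.011). In edgeR 0 of 18 sugar and amino acid transport genes rose (2 over the list alone; adjusted p = 0.0107) and 0 of 30 oxidative phosphorylation genes (0 over the list alone; adjusted p = 0.0145). Unadjusted p was under 0.05 for 6 transport and 5 oxidative phosphorylation genes, all higher, and DESeq2 called 4 and 3. Cd36 (2.30 ± 0.56), Cyp4a10 (3.24 ± 0.44) and Vdr (1.03 ± 0.19) were among those that rose. Brush border digestion had 0 of 21 called in either adjustment (5 higher and 1 lower at an unadjusted p under 0.05, and in DESeq2), with a median of 0.24 and Sis at -1.20 ± 0.46 (adjusted p = 0.126). No proliferation or lipid gene was called without either WT library, Cdx2 KO replicate 3 or either Eed KO library. Without Cdx2 KO replicate 2, 2 proliferation genes fell and 5 lipid, 2 transport, 3 oxidative phosphorylation and 2 brush border genes rose. Without either WT library or Cdx2 KO replicate 3, 1 xenobiotic and 1 fatty acid gene rose. Iron and calcium genes rose in 0 cases without either WT library and 1 without Cdx2 KO replicate 3, and fell in 0 without any library but Cdx2 KO replicate 2. Without DKO replicate 1, 1 lipid, 0 xenobiotic and 1 fatty acid gene rose.

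In DKO against Cdx2 KO 4 of 26 interferon and MHC genes rose, H2-Aa (3.38 ± 0.77), H2-Ab1 (2.82 ± 0.63), Cd74 (2.43 ± 0.61) and Ciita (2.20 ± 0.50) (6 adjusted over the list alone; camera, adjusted p = 0.0514). H2-Aa was at 555 ± 490.0 CPM in DKO. The hormone genes Gip (1.66 ± 0.23) and Cck (2.18 ± 0.31) were 2 enteroendocrine genes of 20 that rose (3 adjusted over the list alone; adjusted p = 0.00211, and adjusted p = 0.686 with an estimated correlation). CDK inhibitors gave Cdkn2a alone (2 rising and 1 falling adjusted over the list alone; adjusted p = 0.000538, and adjusted p = 0.474 with an estimated correlation). PRC2 subunits gave 1 rising and 2 falling of 12 (2 and 6 adjusted over the list alone; adjusted p = 0.0476, and adjusted p = 0.686 with an estimated correlation), with Eed at -1.92 ± 0.20. p53 targets rose in 3 of 18 cases (7 adjusted over the list alone; camera, adjusted p = 0.0691). The chaperone genes Hspa5 (-1.17 ± 0.22), Hsp90b1 (-1.22 ± 0.23) and Pdia4 (-1.18 ± 0.21) were the 3 of 19 unfolded protein genes that fell (4 fell and 2 rose adjusted over the list alone; camera, adjusted p = 0.132). Apart from Cdkn2a, which rose in every case, no gene of these 2 paragraphs' lists was called without DKO replicate 2, and without Cdx2 KO replicate 1 the exceptions were Cdkn2a and 1 falling PRC2 subunit. Interferon and MHC genes also rose in 0 cases without WT replicate 1, WT replicate 2 or Cdx2 KO replicate 3 and in 1 without Cdx2 KO replicate 2 or either Eed KO library. p53 targets rose in 0 without Cdx2 KO replicate 3 or DKO replicate 1 and in 1 without either WT library. Enteroendocrine genes rose in 5 cases without Cdx2 KO replicate 3. PRC2 subunits fell in 6 cases without Cdx2 KO replicate 2 and 1 without Cdx2 KO replicate 3 or any WT or Eed KO library, and rose in 0 without Cdx2 KO replicate 3, DKO replicate 1 or either WT library. The unfolded protein genes fell in 1 case without either WT library or DKO replicate 1 and in 0 without Cdx2 KO replicate 3.

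The genes that were lower in Cdx2 KO than in WT and higher in DKO than in Cdx2 KO numbered 179 of 1865. The sugar transporter family gene Slc5a4b was 241 ± 18.0 CPM in WT, 1.53 ± 0.752 in Cdx2 KO, 371 ± 13.1 in Eed KO and 21.3 ± 7.23 in DKO (3.82 ± 0.37 in DKO against Cdx2 KO). The retinol dehydrogenase gene Rdh16 (3.32 ± 0.37), Unc93a (4.01 ± 0.57) and the acyl-CoA synthetase gene Acsm5 (2.82 ± 0.61) were among the 10 with the largest changes. So were the carnitine synthesis gene Bbox1 (3.16 ± 0.64), the proton channel gene Otop3 (2.95 ± 0.54), Plekhf1, H2-Aa and H2-Bl (4.01 ± 0.91), and Ttll2, at least 5.29-fold higher. H2-Bl reads may be shared with near-identical MHC class I genes. Over the 179 genes the median was -1.999 in Cdx2 KO against WT, 1.53 in DKO against Cdx2 KO and -0.24 in DKO against WT. That was a median of 86.9% of the fall regained. The other 1686, which were not called higher in DKO than in Cdx2 KO, regained 13.3%. The sets were split by the same change that gives this share, so the gap between them follows from the split. In DKO 47 of the 179 still lay lower than WT, and 60 fell in DKO against Eed KO. Independent draws would share 61.1 genes. The reverse was seen too: 99 genes rose in Cdx2 KO and fell in DKO against Cdx2 KO (79.8 by independent draws), with a median of 110.3% of the rise undone, while 52 fell in both (73.6) and 36 rose in both (66.3). The Cdx2 KO libraries are in both comparisons with opposite sign, which alone gave a covariance across genes of -0.0811 in 20 simulations where -0.368 was observed (Pearson's r -0.385 and -0.237). The simulations gave 0 shared genes, but holding no effect they call almost no genes, so this does not measure how far shared libraries raise the overlap. Part of the overlap may come from them, and they are too few to split. Whether a different share of crypt cells in DKO bears on these genes was not tested. Proliferation genes stood at 1.93, 1.21 and 2.30 against the WT mean in Cdx2 KO replicates 1, 2 and 3, and at 0.78 and -0.94 in DKO. The interaction was positive for 174 of the 179 genes and below an unadjusted p of 0.05 for 102, with none passing adjustment over all genes. The 179 genes were picked for low values in the same Cdx2 KO libraries and for a rise from them in DKO. The share regained and the sign of the interaction thus lean upward by that choice, and so does the share undone in the 99. The number was 42 and 31 without WT replicate 1 or 2, 7, 315 and 48 without Cdx2 KO replicate 1, 2 or 3, 118 without Eed KO replicate 1, 100 and 2 without DKO replicate 1 or 2, and 1 with the compared libraries alone.

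**Figure D4:**
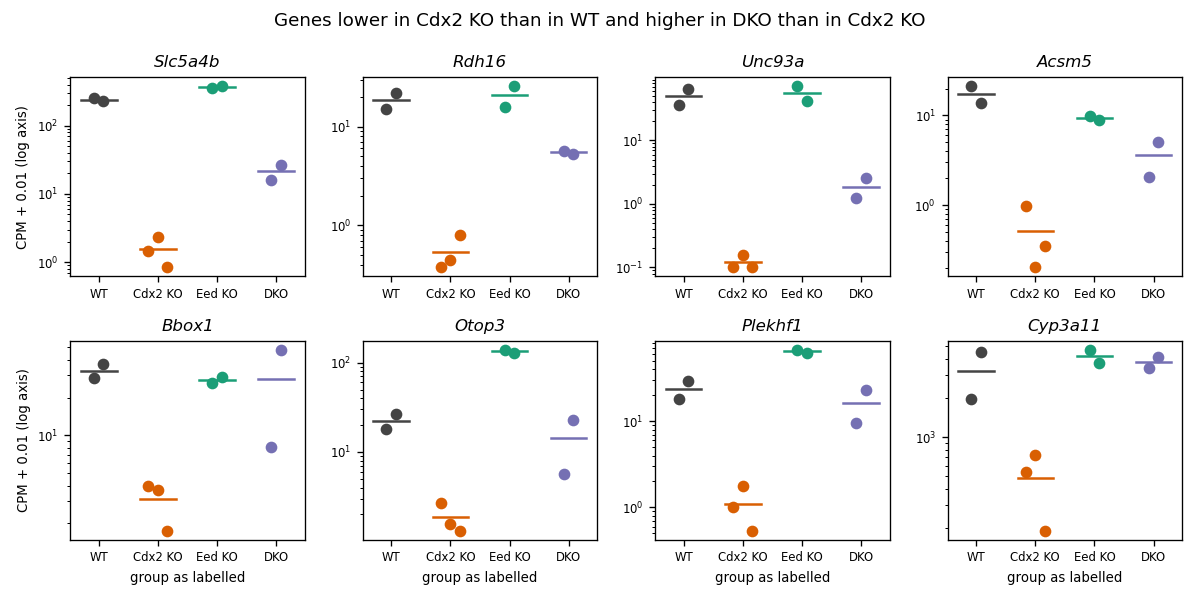
CPM plus 0.01 on a log axis (vertical) in each library of the 4 groups as labelled (horizontal) for 8 genes lower in Cdx2 KO than in WT and higher in DKO than in Cdx2 KO; points are libraries and lines group means. Cyp3a11 had means of 3243, 489.5, 4182 and 3758 CPM in WT, Cdx2 KO, Eed KO and DKO, and Slc5a4b of 241, 1.53, 371 and 21.3.

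The Eed effect was set beside itself in the same way. Over the 1376 genes called in Eed KO against WT, 1241 (90.2%) had the same sign in DKO against Cdx2 KO, with a slope of 0.439 and Pearson's r of 0.767 across genes. Of the genes that fell in Eed KO 311 also fell in DKO against Cdx2 KO (33.3 by independent draws), and 97 rose in both (17.4), Cdkn2a and Cck among them. Suz12 stood at -0.76 ± 0.21 in the second comparison (adjusted p = 0.0634). Cdx2 KO and Eed KO, which share the WT libraries, had 235 falling genes in common (119.4 by independent draws) and 218 rising (81.6). Simulations of shared controls alone gave 0 and 0.05, but they call almost no genes, so this does not measure how far shared libraries raise the overlap. Fabp6, Pla2g4c and Hnf4g fell in both, and Scarb1 and Spink4 rose in both. The covariance was 0.565 where shared controls alone gave 0.121, and Pearson's r 0.310 where they gave 0.551. Part of this overlap may come from the shared WT libraries.

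DKO was compared with WT for the effect of both losses together. Sis changed by -7.24 ± 0.64, with Enpp7 at -8.19 ± 0.78 and Fabp6 at -11.14 ± 0.74. Cdkn2a rose by 7.04 ± 0.48. Ctse rose by 7.85 ± 0.45 and Sult1c2 by 9.46 ± 0.52. Tff2 had a ratio of 5796 (95% counting interval 1040.0 to 228977), Dpcr1, a mucin-like gene, was at least 408-fold higher and Fga at least 304-fold higher. In edgeR 1624 genes rose and 1813 fell, 1372 and 1146 at least 2-fold. With upper-quartile scaling 2079 rose and 1346 fell, 60.7% higher in place of 47.3%, with the median of all genes moved by 0.172. The calls were 544 and 798 without WT replicate 1, 693 and 1007 without WT replicate 2, 991 and 907 without DKO replicate 1, and 1147 lower without DKO replicate 2. Stomach genes rose in 16 of 19 cases (17 adjusted over the list alone), with a median of 8.34, or 7.85 at the bounds (camera, adjusted p = 1.23e-17, and adjusted p = 0.259 with an estimated correlation). Brush border genes fell in 14 of 21 cases (14 fell and 1 rose adjusted over the list alone; adjusted p = 5.05e-08, and adjusted p = 0.549 with an estimated correlation). They fell in 9 cases without either WT library and 8 without DKO replicate 1.

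Goblet genes rose in 14 of 17 cases in DKO against WT and 1 fell, as adjusted over the list alone, Spink4 by 3.22 ± 0.30 (adjusted p = 7.63e-07, and adjusted p = 0.422 with an estimated correlation). Tuft genes rose in 9 of 13 cases (11 adjusted over the list alone; adjusted p = 0.00128, and adjusted p = 0.864 with an estimated correlation), with Avil at 2.22 ± 0.52. CDX2 targets fell in 10 and rose in 1 of 19 (11 and 2 adjusted over the list alone; adjusted p = 0.00018, and adjusted p = 0.549 with an estimated correlation). Ileal genes fell in 5 of 9 cases (7 fell and 1 rose adjusted over the list alone; adjusted p = 0.00114, and adjusted p = 0.484 with an estimated correlation). The origin of the WT piece along the intestine may bear on this fall as well. Interferon and MHC genes rose in 10 and fell in 1 of 26 (14 and 1 adjusted over the list alone), Gbp2 by 4.74 ± 0.44 (adjusted p = 0.00024, and adjusted p = 0.821 with an estimated correlation). Fetal genes rose in 10 and fell in 2 of 21 (11 and 2 adjusted over the list alone; adjusted p = 0.0309, and adjusted p = 0.864 with an estimated correlation). Cholesterol genes rose in 3 and fell in 1 of 18 (7 and 1 adjusted over the list alone; adjusted p = 0.0164, and adjusted p = 0.917 with an estimated correlation). Transport genes fell in 4 and rose in 1 of 18 (4 and 1 adjusted over the list alone; adjusted p = 0.0124, and adjusted p = 0.864 with an estimated correlation). Stroma genes rose in 2 of 6 (2 adjusted over the list alone; adjusted p = 0.00324, and adjusted p = 0.291 with an estimated correlation). Of 11 B cell, plasma cell and myeloid genes 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera, adjusted p = 0.4). With WT replicate 1, WT replicate 2, DKO replicate 1 or DKO replicate 2 left out, goblet genes rose in 11, 7, 10 and 9 cases, tuft genes in 0, 3, 8 and 0, and interferon genes in 3, 10, 8 and 6. In the same order fetal genes rose in 2, 4, 4 and 6 cases and cholesterol genes in 9, 0, 1 and 2. CDX2 targets fell in 6, 8, 6 and 8 of these cases and ileal genes in 3, 4, 1 and 5, and B cell and myeloid genes rose in 0, 0, 1 and 2.

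**Figure D5:**
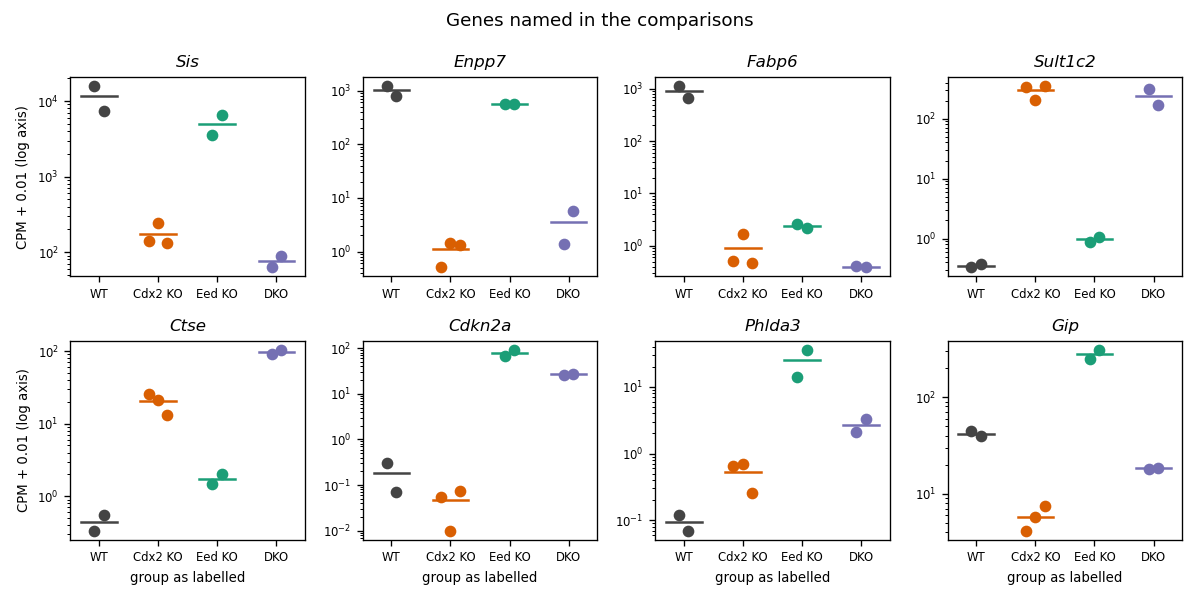
CPM plus 0.01 on a log axis (vertical) in each library of the 4 groups as labelled (horizontal) for 8 named genes; points are libraries and lines group means. Sis had a mean of 11489 CPM in WT and 174 in Cdx2 KO, and Cdkn2a of 79.5 in Eed KO and 26.7 in DKO.

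The interaction asked whether the Cdx2 effect differs with and without Eed, as the change in DKO against Eed KO minus that in Cdx2 KO against WT. Cd97, an adhesion G protein-coupled receptor, stood at 3.56 ± 0.19 in Cdx2 KO against WT and 0.63 ± 0.18 in DKO against Eed KO, an interaction of -2.93 ± 0.25 (adjusted p = 0.0183). The value in DKO against Eed KO did not pass (adjusted p = 0.0537). Cd97 was the named gene that passed; the other, 9530053A07Rik, was named after its values were seen. In edgeR 0 genes were higher and 2 lower, with 715 higher and 783 lower at an unadjusted p under 0.05, and DESeq2 called 105 and 143. Of the 179 recovered genes none passed. The lower calls numbered 1 without Cdx2 KO replicate 1 or replicate 2 and 0 without any other library, and 1 was higher without Cdx2 KO replicate 2. In data simulated on these libraries, 0 of 100 genes with a 2-fold interaction and 20 of 100 with a 4-fold interaction were called. By camera 11 lists differed, and none did with an estimated correlation. In the other comparisons camera called 16 lists in Cdx2 KO against WT, 12 in Eed KO against WT and 11 in each of the 3 DKO comparisons, with its preset correlation of 0.01, and every one of those calls was lost with an estimated correlation. The rotation test fry, which asks whether a list moves on balance one way, called 8 lists in Cdx2 KO against WT, 3 in Eed KO against WT, 7 in DKO against WT, 1 in DKO against Cdx2 KO and 5 in DKO against Eed KO. List directions are therefore descriptions of these libraries, with stomach genes such as Sult1c2 and Ctse the plainest case. In that list the filter on low counts favoured genes that could rise but not fall.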

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

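Every test of an explanation in this part was devised after the pattern it concerns had been seen. The results listed first were picked out because the effect of the Cdx2 label differed between mice with and without Eed, by a test of the interaction in edgeR or camera. Cd97, an adhesion receptor of leukocytes and epithelium, differed by -2.93 on the log2 scale (adjusted p = 0.0183), and 9530053A07Rik, a gene of unnamed function, by -5.74 (adjusted p = 0.0387). Cd97 was at a mean of 5.23 CPM in WT, 61.7 in Cdx2 KO, 15.3 in Eed KO and 23.8 in DKO, while 9530053A07Rik was at 66.8 CPM in Eed KO and 1.14, 1.22 and 1.32 in WT, Cdx2 KO and DKO.

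Lists with a positive interaction by camera were brush border digestion (adjusted p = 0.000105), sugar and amino acid transport (adjusted p = 0.000141), oxidative phosphorylation (adjusted p = 0.000178), xenobiotic metabolism (adjusted p = 0.00083) and ileal uptake (adjusted p = 0.00172), with medians of 0.85, 0.80, 0.39, 0.54 and 0.55. Lists with a negative interaction were p53 targets (adjusted p = 3.93e-08), goblet cells (adjusted p = 1.4e-06), fetal and injury-associated epithelium (adjusted p = 0.000665), crypt stem cells (adjusted p = 0.000665), enteroendocrine cells (adjusted p = 0.000958) and proliferation (adjusted p = 0.00175), with medians of -1.09, -1.20, -1.67, -1.50, -1.15 and -0.97. With 1 library left out the positive medians ran from 0.20 to 1.21, 0.46 to 1.12, 0.23 to 0.51, 0.23 to 0.67 and 0.40 to 0.77 in that order. The negative ones ran from -1.31 to -0.60, -1.57 to -0.93, -2.11 to -0.81, -2.46 to -0.61, -1.44 to -0.63 and -2.04 to 0.43, so the sign turned for proliferation. No member of any of these lists was called in edgeR over all genes, while 9 p53 targets, 5 goblet genes and 2 fetal genes were lower and 1 ileal gene higher adjusted over the list alone. With an estimated correlation adjusted p was 0.701 for p53 targets, goblet cells and ileal uptake and 0.857 for the others. Unadjusted p was under 0.05 for 5 brush border genes, 3 transport genes, 4 oxidative phosphorylation genes, 4 xenobiotic genes and 3 ileal genes, all higher, and for 9 p53, 9 goblet, 5 fetal, 1 crypt stem, 4 enteroendocrine and 3 proliferation genes, all lower, with 1 p53 gene higher. DESeq2 called 0, 0, 3, 2 and 1 of the first lists and 6, 1, 2, 0, 0 and 0 of the second.

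The rise of p53 targets in Eed KO was weighed first. An effect of tamoxifen or Cre alone would raise them as much in Cdx2 KO. The median over all 18 tested members was 0.106 (SE 0.432) there, against 1.47 in Eed KO and 0.427 in DKO. These values argue against such an effect as the whole cause. They do not exclude it, because the SE is over genes that may move together. p53 targets also fell in DKO against Eed KO, so a lowering by the Cdx2 label could hide a rise. With either Eed KO library left out, members of the list were still called higher, which argues against 1 Eed KO library as the whole cause. It does not exclude that cause, since each such fit holds 1 Eed KO library and the members may move together. An earlier test of medians by library, 0.958 (SE 0.551) and 1.77, had not decided this. The count of called members was taken up after both were known. Without WT replicate 1 0 members were called, but 1 gene rose in that whole fit, and the median was 0.915 or more with any library left out. A tamoxifen effect that needs intact Cdx2 was not tested and stays open, as does a response to lost PRC2.

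The rise of crypt and proliferation genes in Cdx2 KO was weighed next. Whole crypts carried into the villus fraction would bring Paneth cell genes with them. In replicates 1 and 2 the Paneth median was -0.0680 (SE 0.566), while proliferation and crypt stem genes stood at 1.52 each. That median argues against whole crypts there. It does not exclude them, since 2 Paneth genes were still called higher and 0 lower. An effect of Cdx2 loss on Paneth genes was not tested. Paneth genes were 3.24 higher in replicate 3 than in replicates 1 and 2 (median log2 difference), with stem genes 1.38 and proliferation genes 0.747 higher, and more whole crypts in replicate 3 would fit this. Upper-crypt cells without Paneth cells, or dividing cells on the villus, also stay open for replicates 1 and 2.

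The last was the fall of Fabp6 and Slc10a2 in Eed KO, where the median of the ileal list of 9 was -0.984 (SE 1.37) and a WT piece taken nearer the ileum would lower it all. That origin of the WT piece and an effect of Eed loss cannot be told apart, because the spread is wider than the value and the origin of the piece is tied to the WT label. The jejunal regulator Gata4 stood at 0.03 (SE 0.18) and Fabp6 at 671 CPM or more in both WT libraries and 2.56 or less elsewhere. With either WT library left out 1 of the 9 genes was called, Fabp6, and against the Eed KO mean their median was 0.375 (SE 1.56) in the lower WT library and 0.838 in the other, so 1 WT library as the cause stays open for the list. The rule of that test, which needs more than 1 gene to exclude, was changed after its first run, which had counted that wide SE as a fit.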

How the results depend on the processing

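The alternatives were fixed before the data were examined, except for leaving only Cdx2 KO number 2, which was chosen after the Xist reads were seen. Depth and 5 residual degrees of freedom limit small changes, and where a group is left with 1 library that library is assumed to vary like the others. Where no construction is named below, the cause was not tested. No named gene that was called turned its direction except in that last setting. Of the named results the same call was kept by 879 of 886 with relative log expression, 851 with upper-quartile scaling and 807 with no filter, by 872 of 877 with a stricter filter, by 774 of 865 in DESeq2 by 624 of 732 with only the groups compared, and by 688 (without WT replicate 1) to 834 (without Cdx2 KO replicate 2) of 886 with 1 library left out. Upper-quartile scaling lowered the falling genes of Eed KO against WT to 510. With no filter the interaction gave 12 higher and 11 lower. DESeq2 called 1030 and 1268 in Eed KO against WT, 1122 and 1308 in DKO against Cdx2 KO, 986 and 1300 in DKO against Eed KO, 105 and 143 in the interaction and 448 recovered genes. Only the groups compared, a fit with fewer libraries, gave 8 and 3 in DKO against Cdx2 KO and 1 recovered gene; the interaction needs all 4 groups and was not run so. With the replicate block, although the numbers pair nothing and deviations of like numbers correlated at -0.197 (WT and Eed KO), 0.232 (WT and DKO) and -0.101 (Eed KO and DKO), and those of Cdx2 KO replicates 1 and 2 at -0.0909 and 0.0309 with WT, 0.0672 and -0.1004 with Eed KO and 0.0071 and 0.290 with DKO, DKO against Cdx2 KO gave 26 and 6, the interaction 1 and 4, and 13 genes recovered. Leaving only Cdx2 KO number 2 gave 630 and 769 in Cdx2 KO against WT, 15 and 8 in DKO against Cdx2 KO, 3 and 8 in the interaction and 6 recovered genes, and turned Xist to -0.84 in Cdx2 KO against WT and 11.08 in DKO against Cdx2 KO, as that library has hardly any Xist reads.

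With 1 library left out, higher and lower genes ranged over 496 to 2135 and 903 to 1908 in Cdx2 KO against WT, 1 to 694 and 1 to 877 in Eed KO against WT, 544 to 1727 and 798 to 1885 in DKO against WT, 6 to 733 and 0 to 861 in DKO against Cdx2 KO, 213 to 717 and 240 to 1056 in DKO against Eed KO, and 0 to 1 each in the interaction. Recovered genes ranged over 2 to 315 and the slope over 0.593 to 0.735. Lists called by camera ranged over 14 to 18, 10 to 14, 10 to 14, 10 to 16, 10 to 14 and 6 to 15 in the order Cdx2 KO, Eed KO and DKO against WT, DKO against Cdx2 KO, DKO against Eed KO and interaction. The cholesterol synthesis list in the interaction had adjusted p from 7.12e-06 (without WT replicate 2) to 0.96 (without Eed KO replicate 1), and turned its direction without WT replicate 1, at adjusted p = 0.0335. With an estimated correlation 0, 0, 0, 0, 0 and 0 lists were called in that order, and by fry 8, 3, 7, 1, 5 and 0. The counts of called genes in every comparison, and of the recovered genes, moved when single libraries were left out. Where that left 1 library in a group, lost power alone could lower them.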

Other observations

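In the libraries labelled Cdx2 KO, some genes of other tissues rose by themselves. Lyve1, known from lymphatic endothelium, went from 3.63 to 618 CPM, while Pecam1, a general endothelial gene chosen after its values were seen, was at 0.349 and 0.207. Ctrb1, a pancreatic chymotrypsinogen, stood at 0.0181 CPM in WT, 26.2 in Cdx2 KO, 0.452 in Eed KO and 70.5 in DKO. In DKO against WT its ratio was 3142 (95% counting interval 564 to 124122). H19 was uneven in Cdx2 KO, at 306 ± 332 CPM, and at 0.0181 in WT.

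Reads of 3 genes of the immune defence families were uneven between libraries, and those of Trim12a and Trim30d were near 0 in some. Trim12a was at 9.97 ± 14.0 CPM in WT, 21.3 ± 8.33 in Cdx2 KO, 0.0851 ± 0.12 in Eed KO and 0.0152 ± 0.0215 in DKO. Trim30d was at 67.5 ± 58.7, 30.4 ± 12.7, 20.5 ± 10.4 and 0.0152 ± 0.0215 CPM in the same order, and H2-Bl at 42.5 ± 14.1, 2.91 ± 1.24, 851 ± 566 and 46.7 ± 55.0. The mice were of mixed strain per the labels.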
